A study of Homo sapiens with 10 samples.

How the data were processed

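RNA from MIA PaCa-2 cells was measured in 10 libraries, 5 of cells in 10 µM hydroxyprogesterone caproate and 5 of cells in DMSO, both for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, poly(A) RNA was selected with oligo(dT) beads, fragmented and reverse-transcribed with random primers, and libraries were sequenced as paired-end reads on an Illumina NovaSeq instrument. The submitters' processing notes name fastp 0.23.2, STAR 2.7.7a, edgeR without a version and the genome build GRCh38.p13, with no role or order. The read counter, the gene annotation and any filter on genes are not given in the sources used here.

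The authors deposited 1 table with FPKM (fragments per kilobase of gene, scaled to library size) for 16734 genes and 10 libraries. By gene ID, 16696 of these genes are protein-coding in GENCODE 29, 10 have another biotype and 28 are not in it. The 344 genes with no symbol in the table were named from the reference table by their ID, and 43 symbols stand for more than 1 gene. Mitochondrial genes carry their MT- symbols. Coordinates are those of GENCODE 29 on GRCh38, whose release can differ from the one behind the deposited table.

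For 15208 genes above 0 in at least 3 libraries, all 15208 had values that were whole multiples of what 1 read is worth in each library, within 0.0001 of a read. For the other 1526 genes the step is not fixed by the data, and their number of reads is a lower limit. The recovered reads summed to between 65851927 and 82219086 per library. Intervals for ratios of reads are exact binomial (Clopper-Pearson) at 95%. Intervals and floors from reads cover counting error only, since reads without molecular identifiers are not independent molecules.

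Values were analysed as log2(FPKM + 0.1), a scale on which the fold change of a low gene is understated. Genes with at least 1 FPKM in at least 5 libraries were tested, 9150 genes that held 98.9% of the FPKM. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated by empirical Bayes with trend and robust options, two-sided) with Benjamini-Hochberg adjustment at 0.05. Of 44 gene lists fixed before the data were examined, 36 had at least 5 tested members and were tested with limma's camera at a preset correlation of 0.01, adjusted over the 36 lists. Counts of higher and lower members adjusted over the list alone were the same for 35 lists, and for the histones 2 members instead of 3 were lower. Lists share members. Camera with an estimated correlation was run beside it and called 0 lists, with 8 at an unadjusted p under 0.05. The fry test, which asks whether the genes of a list move on balance one way and compares it with no other genes, was run as well.

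Library measures were compared with an exact two-sided permutation test of the difference in means over the 252 assignments of 10 libraries to 5 and 5, whose smallest possible p is 0.00794, with Benjamini-Hochberg adjustment over 13 measures. Principal components were taken from the tested genes. Within-group pairs of libraries differed by 12 to 25.7 times the counting noise of the recovered reads (chi-square per degree of freedom), more than counting noise alone gives, so no 2 libraries were taken for copies of 1 library. This does not show that they are independent cultures.

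The genes named were fixed by a rule written before the data were examined. It took 20 genes regardless of their values, the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 1 FPKM in a group and no overlap between the groups, and the 4 members with the smallest p of each called list. Some of the genes the rule took are not reported here. Members outside the rule are said to be named after their values were seen.

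The procedure was tested on simulated data for HPC against DMSO, made from the DMSO means and the real library sizes with a coefficient of variation of 3.49%. Over 8912 genes, 50 genes each were changed by 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 100% of each size were recovered. Of 214 calls, 14 (6.5%) were false. A planted list was called, and so was 1 of the other lists. The simulation changed 200 genes in random directions and drew the noise of each gene separately. In the real data 87.7% of the tested genes were called. The simulation therefore tests neither the scaling between the groups nor the correlation between genes, on which the list calls depend.

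Alternatives changed the pseudocount, the filter on low values, the scaling, the weights, the variance model, the test, the block, the threshold and the libraries included. Added after seeing the data were limma's voom on the recovered reads, a rescaling to the sum over genes not encoded by mitochondria and a loess correction on transcript length and GC content from the GENCODE 29 transcripts. Computations ran in Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.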

Results

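The series asked how the transcriptome of MIA PaCa-2, a human pancreatic ductal adenocarcinoma cell line, responds to hydroxyprogesterone caproate (HPC), a synthetic progestin. Poly(A) RNA was sequenced from 5 libraries of cells kept for 24 h in 10 µM HPC and from 5 libraries of cells kept for the same time in an equal volume of the solvent, DMSO. The deposited table gave FPKM for 16734 genes. Reads recovered from the FPKM values summed to between 71603127 and 82219086 per library in DMSO and between 65851927 and 74477678 in HPC. Libraries of a group correlated with each other at Pearson r of 0.989 to 0.994 over the log2 values of the tested genes, and libraries of different groups at 0.842 to 0.863. The labels call the libraries of a group biological replicates and give no culture day or batch, so the p-values measure the spread between these libraries.

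After 24 h in HPC, libraries held larger shares of endoplasmic reticulum and amino acid stress, antioxidant, metallothionein and immediate early transcripts. They held smaller shares of transcripts of DNA replication, mitosis, respiratory chain and interferon-stimulated genes. FPKM is scaled to library size, so amounts per cell were not measured. Calls of lists, 16 in all, were made with camera at a preset correlation, and with an estimated correlation 0 lists were called (lowest adjusted p = 0.109). Of 9150 genes tested, 3922 were higher and 4099 lower with HPC (limma, Benjamini-Hochberg adjusted p under 0.05). At least 1.5-fold changes were found for 1547 higher and 1861 lower genes, at least 2-fold changes for 690 and 904, and at least 4-fold changes for 182 and 169. In 79.6% of the tested genes the 5 HPC values and the 5 DMSO values did not overlap, against 0.79% given by chance. The first principal component held 91.6% of the variance and separated the groups (mean 41.8 ± 2.51 in HPC and -41.8 ± 0.597 in DMSO, SD, n = 5, exact permutation adjusted p = 0.0129). When the libraries were rescaled to the same sum over genes not encoded by mitochondria, an alternative chosen after seeing the data, the median log2 fold change of the tested genes moved from -0.01 to -0.19 and the share of called genes that were lower from 51.1% to 63.4%. At least 1.5-fold changes were then found for 1089 higher and 2497 lower genes, and 12 lists instead of 9 were shifted up. With 1 FPKM added instead of 0.1, at least 1.5-fold changes were found for 1139 and 1361. Of the genes named by the rule, INSIG1 and FKBP5 turned direction with the non-mitochondrial sum, and the others tested did not.

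Among the lists that rose, the smallest adjusted p was that of the ATF4 amino acid stress list, with 24 tested genes, which holds targets of the transcription factor that acts downstream of phosphorylated eIF2α. All 24 were higher, with a median log2 fold change of 2.78 (camera, adjusted p = 3.34e-10; adjusted p = 0.114 with an estimated correlation). ATF4 itself (chromosome 22, 39519695 to 39522685, GRCh38) rose from 31.4 ± 0.443 to 140 ± 4.22 FPKM (SD, n = 5). DDIT3, which encodes the stress-induced transcription factor CHOP (chromosome 12, 57516588 to 57521737), rose from 0.899 ± 0.0832 to 37.9 ± 3.5 FPKM (log2 fold change 5.25 ± 0.067 SE, adjusted p = 2.95e-15). ASNS, asparagine synthetase (chromosome 7, 97852118 to 97872542), rose from 3.32 ± 0.304 to 51.5 ± 1.68 FPKM (log2 fold change 3.92 ± 0.052 SE, adjusted p = 2.47e-15). CHAC1, which encodes a glutathione-degrading enzyme, rose by 4.00 on the log2 scale, SESN2 by 3.60 and CEBPB by 3.44.

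All 21 unfolded protein response genes were also higher, with a median log2 fold change of 1.14 (camera, adjusted p = 1.2e-06; adjusted p = 0.305 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP (chromosome 9, 125234853 to 125241330), rose from 166 ± 4.65 to 1116 ± 93.5 FPKM (SD, n = 5), which is 6.69-fold on the fitted scale (SE of the log2 fold change 0.049, adjusted p = 5.61e-14). XBP1, a transcription factor of this response, rose from 6.66 ± 0.247 to 44.2 ± 1.27 FPKM, the chaperone gene HYOU1 by 2.29 on the log2 scale and the sensor gene ATF6 by 1.02. The 15 heat shock protein genes, most of which serve the cytosol, split into 9 higher, 5 lower and 1 that did not pass. The list was not called (median 0.33, or 0.16 with the non-mitochondrial sum, camera, adjusted p = 0.21). HSPA6, a heat shock protein gene outside this list, rose from 0.155 ± 0.0768 to 7.95 ± 1.53 FPKM. Its log2 fold change was 5.02 ± 0.23 SE (limma, adjusted p = 9.45e-09), and 2.94 to 5.84 over the alternatives.

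**Figure D1:**
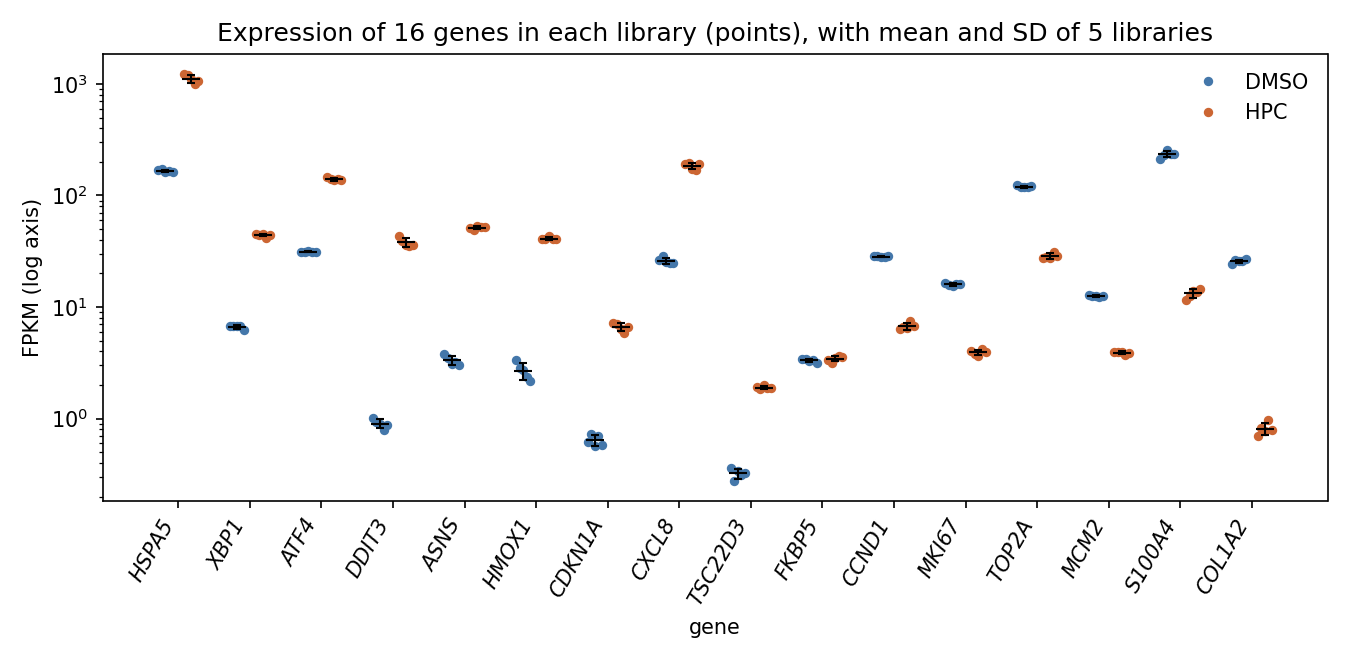
FPKM (log axis) of 16 genes in each of the 5 DMSO and 5 HPC libraries (points), with the mean and SD of each group (black bars). HSPA5 lies near 1116 FPKM with HPC against 166 with DMSO, and the values of FKBP5 overlap between the groups.

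The 14 tested immediate early genes, which encode rapidly induced transcription factors and their regulators, were all higher (median log2 fold change 1.98, camera, adjusted p = 4.32e-06; adjusted p = 0.109 with an estimated correlation). EGR1 rose from 15.1 ± 1.46 to 161 ± 5.44 FPKM (SD, n = 5), JUN from 19.8 ± 0.509 to 86.8 ± 6.15 FPKM and JUND from 38.4 ± 1.3 to 116 ± 3.5 FPKM. Of 20 NRF2 antioxidant genes, 16 were higher, 2 lower and 2 did not pass (median 1.05, adjusted p = 0.000333; adjusted p = 0.109 with an estimated correlation). HMOX1, heme oxygenase 1 (chromosome 22, 35380361 to 35394214), rose from 2.69 ± 0.467 to 41.1 ± 1.19 FPKM (log2 fold change 3.90 ± 0.096 SE, adjusted p = 9.67e-12). SRXN1, which encodes sulfiredoxin, rose by 3.30 on the log2 scale, GCLC, a subunit of the enzyme that starts glutathione synthesis, by 2.50, and FTL, the ferritin light chain, from 3150 ± 142 to 8805 ± 246 FPKM. NQO1, another gene of this list, fell by 0.25 on the log2 scale (adjusted p = 1.54e-07), a gene chosen after its values were seen.

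Of the 8 tested genes for metallothioneins and zinc transport, 7 were higher and 1 lower (median log2 fold change 3.09, camera, adjusted p = 0.00969; adjusted p = 0.212 with an estimated correlation). SLC30A1, a zinc exporter, rose from 5.81 ± 0.265 to 55.5 ± 1.64 FPKM (SD, n = 5), MT1X from 3.62 ± 0.341 to 49.2 ± 1.65 FPKM and MT2A from 45.8 ± 4.76 to 326 ± 17.1 FPKM. The zinc importer SLC39A10 fell from 32.9 ± 1.30 to 20.2 ± 0.528 FPKM. Metallothionein genes are near-identical copies, so reads can be shared among them and their separate levels are uncertain. Of 18 genes of the NF-kB and inflammatory cytokine list, 12 were higher, 2 lower and 4 did not pass (median 1.38, or 0.38 with no filter, adjusted p = 0.00233; adjusted p = 0.212 with an estimated correlation). The chemokine gene CXCL8 rose from 26.0 ± 1.62 to 185 ± 12 FPKM, TRAF1 by 2.95 on the log2 scale, LIF by 2.46 and CXCL5 by 1.44.

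Of 23 p53 target genes, 17 were higher, 4 lower and 2 did not pass (median log2 fold change 0.99, camera, adjusted p = 0.003; adjusted p = 0.212 with an estimated correlation). CDKN1A, which encodes the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 0.640 ± 0.0723 to 6.63 ± 0.546 FPKM (SD, n = 5). GADD45A rose by 3.27 on the log2 scale and the death receptor gene TNFRSF10B by 2.6. SESN2 is a member of both this list and the ATF4 list. Of 12 hypoxia response genes, 10 were higher, 1 lower and 1 did not pass (median 0.46, or 0.30 with the non-mitochondrial sum, adjusted p = 0.016; adjusted p = 0.367 with an estimated correlation), among them VEGFA (log2 fold change 2.53), SLC2A1 (1.07), SLC2A3 (0.98) and KDM3A (0.67). This call was lost with a filter of at least 5 FPKM (adjusted p = 0.109, within a range of 0.0014 to 0.109 over the alternatives at the preset camera correlation). Of 30 ribosome biogenesis and MYC target genes, 24 were higher, 2 lower and 4 did not pass (median 0.33, or 0.16 with the non-mitochondrial sum, adjusted p = 0.000333; adjusted p = 0.209 with an estimated correlation). MYC rose from 10.8 ± 0.426 to 20.6 ± 0.760 FPKM, ODC1, the first enzyme of polyamine synthesis, by 1.53 on the log2 scale, RRP9 by 1.28 and RRP12 by 1.2.

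Proliferation genes fell. All 28 mitotic genes were lower (median log2 fold change -1.24, camera, adjusted p = 3.46e-09; adjusted p = 0.212 with an estimated correlation). MKI67, which encodes the proliferation antigen Ki-67 (chromosome 10, 128096659 to 128126385), fell from 16 ± 0.384 to 3.93 ± 0.210 FPKM (SD, n = 5). The topoisomerase gene TOP2A fell from 120 ± 2.52 to 28.6 ± 1.61 FPKM, KIF20A from 12.8 ± 0.449 to 2.26 ± 0.119 FPKM and ANLN from 19.8 ± 0.963 to 5.05 ± 0.117 FPKM. Of 29 DNA replication and G1/S genes, 27 were lower, 1 higher and 1 did not pass (median -1.38, adjusted p = 1.15e-07; adjusted p = 0.109 with an estimated correlation). The higher one was CDC6 (log2 fold change 0.21) and the one that did not pass CCNE1 (adjusted p = 0.156), both named after their values were seen. The helicase subunit genes MCM2 and MCM4 fell by 1.67 and 1.70 on the log2 scale, UHRF1 by 2.23 and the licensing factor gene CDT1 by 1.68. CCND1, cyclin D1 (chromosome 11, 69641087 to 69654474), fell from 28.4 ± 0.457 to 6.76 ± 0.483 FPKM (log2 fold change -2.06 ± 0.041 SE, adjusted p = 5.32e-14). It belongs to the list of cell cycle inhibitors and G1 cyclins, of whose 12 members 4 were higher and 8 lower, with no call (median -0.30, or -0.46 with the non-mitochondrial sum, mean -0.013, camera, adjusted p = 0.287).

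**Figure D2:**
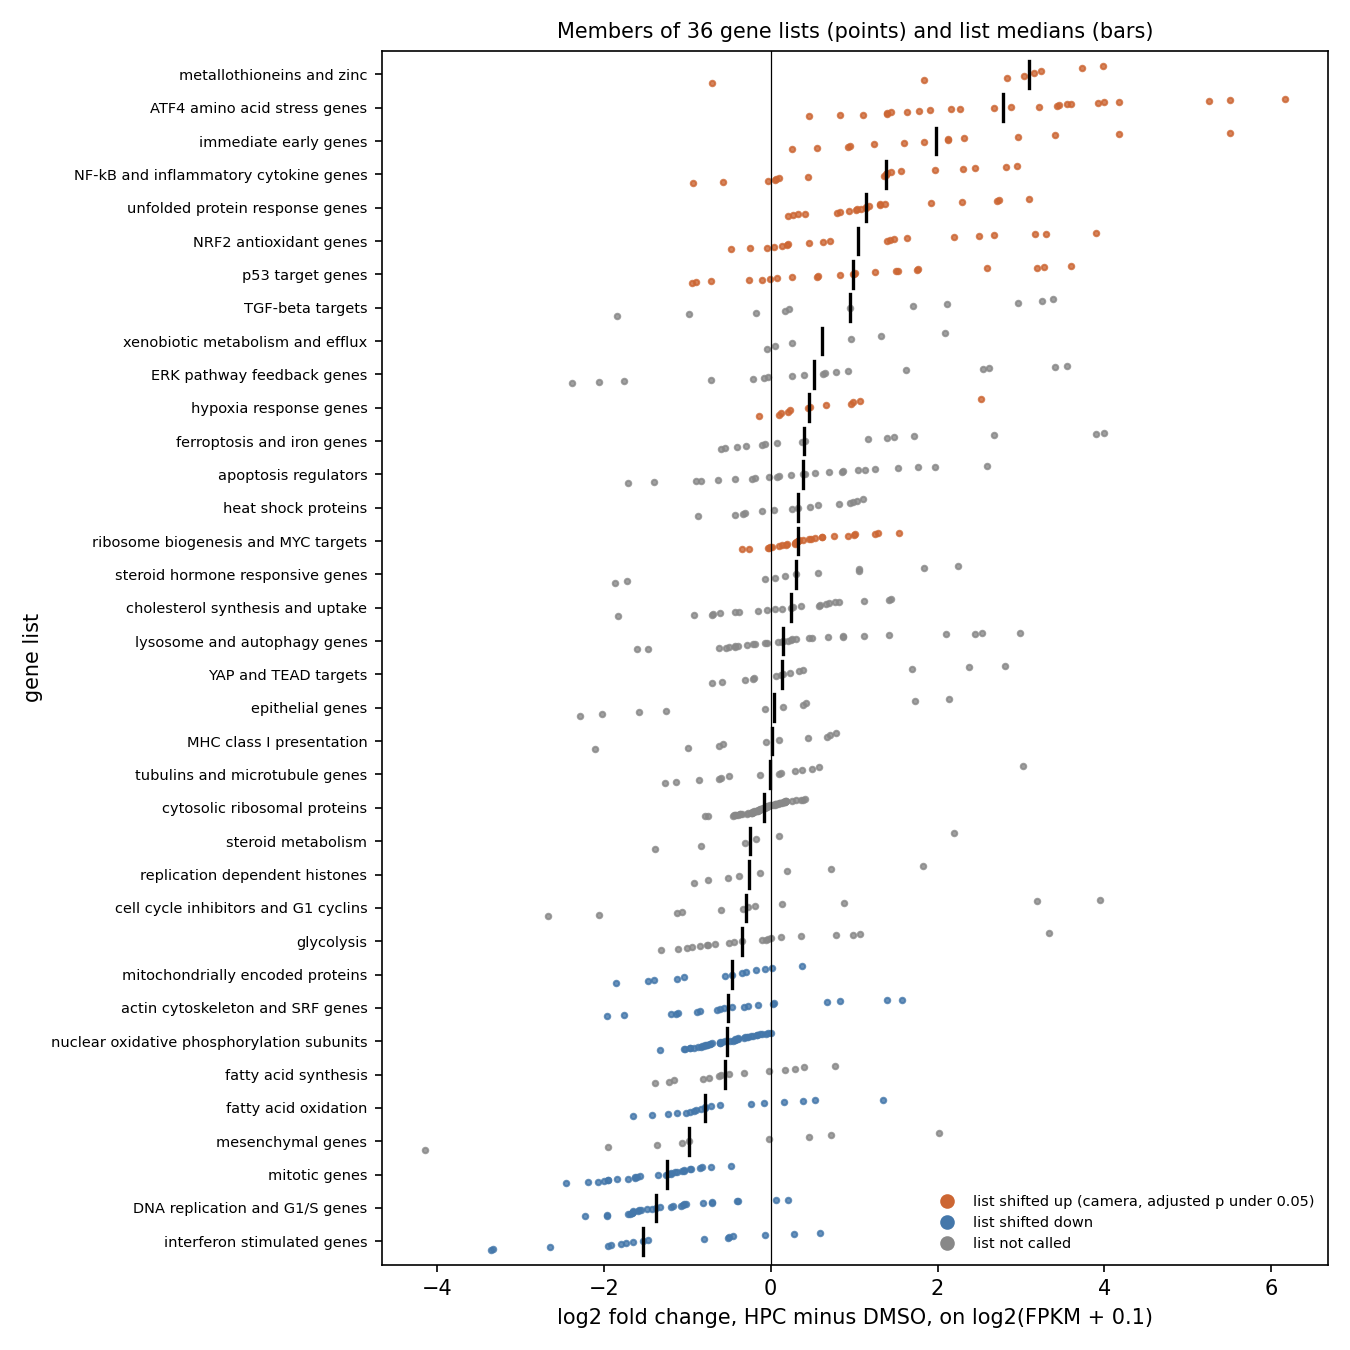
Log2 fold change (HPC minus DMSO, on log2 of FPKM plus 0.1) of each tested member (points) of 36 gene lists, with the list median (black bar). Orange lists were shifted up and blue lists down by camera at an adjusted p under 0.05, and grey lists were not called. With an estimated correlation 0 lists were called. The ATF4 list has a median of 2.78 and the mitotic list one of -1.24.

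Most genes of mitochondrial energy metabolism were lower. Of 42 nuclear oxidative phosphorylation subunits, 39 were lower and 3 did not pass (median log2 fold change -0.52, camera, adjusted p = 1.64e-07; adjusted p = 0.109 with an estimated correlation). The ATP synthase subunit genes ATP5F1A, ATP5F1C, ATP5MC3 and ATP5PB fell by 0.92, 0.83, 1.04 and 0.79 on the log2 scale. Of 19 fatty acid oxidation genes, 15 were lower and 4 higher (median -0.79, adjusted p = 0.0123; adjusted p = 0.179 with an estimated correlation). ECHS1 fell from 150 ± 3.44 to 74.1 ± 2.08 FPKM (SD, n = 5), HADHA from 22.9 ± 0.459 to 10.5 ± 0.494 FPKM, HADH by 1.65 on the log2 scale and ETFB by 0.96. PLIN2, which coats lipid droplets, rose by 1.35 on the log2 scale, a member named after its values were seen. This list lost its call with a filter of at least 5 FPKM (adjusted p = 0.229, within a range of 0.00353 to 0.229 over the alternatives at the preset camera correlation).

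The 13 mitochondrially encoded genes held 14.8% ± 0.717 of the FPKM total in HPC and 22.6% ± 0.704 in DMSO (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0129). Of the 13, 10 were lower, 1 higher and 2 did not pass (median log2 fold change -0.47, camera, adjusted p = 0.0212; adjusted p = 0.563 with an estimated correlation), and the list lost its call after quantile normalization (median -0.20, adjusted p = 0.285, within a range of 0.00655 to 0.285 over the alternatives at the preset camera correlation). The changes were unequal along the chromosome. MT-CO3 fell from 5212 ± 211 to 1985 ± 121 FPKM, MT-CYB from 857 ± 9.94 to 312 ± 33.1 FPKM, and MT-ATP8 and MT-ATP6, whose reading frames overlap, by 1.13 and 1.04 on the log2 scale. MT-ND3, named after its values were seen, had a log2 fold change of -1.85 ± 0.073 SE. In contrast MT-ND1 rose from 1227 ± 50.2 to 1591 ± 48.6 FPKM (log2 fold change 0.38 ± 0.030 SE, adjusted p = 5.32e-08), and MT-ND2 and MT-ND4 did not pass (adjusted p = 0.179 and 0.814), all 3 also named after their values were seen. After quantile normalization MT-ND4L turned from -0.17 to 0.07, MT-CO2 moved from -0.30 to 0, MT-CO1 from -0.35 to -0.02, MT-ND5 from -0.47 to -0.07, MT-ND2 from -0.06 to -0.20 and MT-ND4 from 0.01 to 0.45. With libraries scaled to the non-mitochondrial sum MT-ND1 moved to 0.21, MT-ND2 to -0.23 and MT-ND4 to -0.16, and with TPM rescaling MT-ND4 turned to -0.02.

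**Figure D3:**
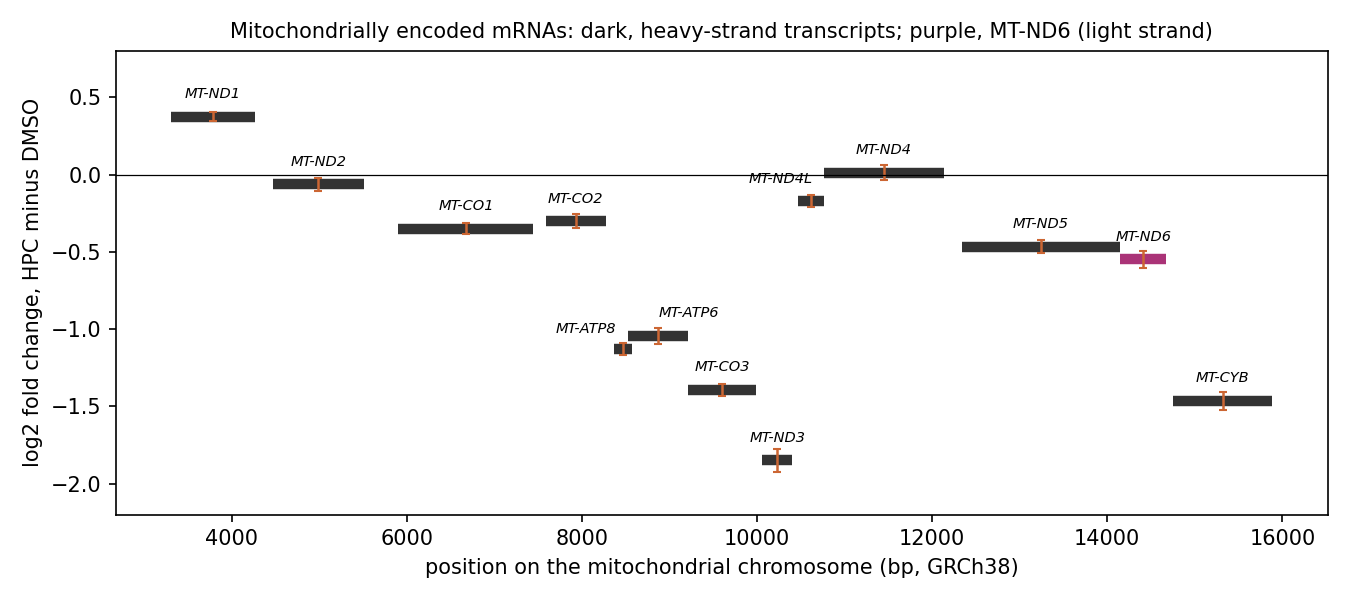
Log2 fold change (HPC minus DMSO) of the 13 mitochondrially encoded genes against their position on the mitochondrial chromosome (bp, GRCh38). Each horizontal bar spans a gene and the orange bar is the SE. MT-ND1 lies at 0.38 and MT-ND3 at -1.85, and after quantile normalization MT-ND4L turned to 0.07 and MT-CO2, MT-CO1 and MT-ND5 moved to 0, -0.02 and -0.07. MT-ND4, at 0.01 here, moved to 0.45 after quantile normalization and turned to -0.16 with libraries scaled to the non-mitochondrial sum and to -0.02 with TPM rescaling.

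Of 17 interferon-stimulated genes, 14 were lower, 2 higher and 1 did not pass (median log2 fold change -1.53, or -0.87 with no filter, camera, adjusted p = 0.00214; adjusted p = 0.209 with an estimated correlation). The higher ones were IRF1 (log2 fold change 0.60) and IFI35 (0.28) and the one that did not pass IFIT5 (adjusted p = 0.255), all named after their values were seen. IFIT1 fell from 9.85 ± 0.552 to 2.76 ± 0.152 FPKM (SD, n = 5) and IFIT2 from 12 ± 0.425 to 3.76 ± 0.170 FPKM. RIGI, which encodes a viral RNA sensor, fell from 8.28 ± 0.311 to 2.08 ± 0.177 FPKM, and OAS3 by 3.33 on the log2 scale. The MHC class I presentation list split into 5 higher, 4 lower and 1 that did not pass, and was not called (median 0.02, which turned to -0.14 with the non-mitochondrial sum and -0.01 with TPM rescaling, adjusted p = 0.995). Of 20 actin cytoskeleton and SRF genes, 14 were lower, 4 higher and 2 did not pass (median -0.51, adjusted p = 0.0465; adjusted p = 0.305 with an estimated correlation). ACTG1, cytoplasmic gamma actin, fell from 144 ± 2.84 to 78.2 ± 1.87 FPKM and VCL, vinculin, from 23.2 ± 0.759 to 6.77 ± 0.335 FPKM, whereas FHL2 rose by 1.58 on the log2 scale. The call of the actin list was lost when any 1 of the 5 HPC libraries was left out (adjusted p = 0.0627, 0.0648, 0.0756, 0.0535 and 0.0674 without HPC replicates 1 to 5) and with TPM rescaling (0.0508), no filter (0.11), no trend or robust step (0.0553) or the non-mitochondrial sum (0.089). It was also lost with a replicate block (0.0548, and 0.0578 with TPM rescaling added). Fewer genes passed the filter when a library was left out, so those fits changed the genes tested as well. Over the alternatives at the preset camera correlation the adjusted p of the actin list ranged from 0.0211 to 0.11.

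Genes tied to steroid hormones and sterols, the class to which HPC belongs, moved in both directions. Of 11 tested steroid hormone responsive genes, 7 were higher, 2 lower and 2 did not pass, and the list was not called (median log2 fold change 0.30, or 0.13 with the non-mitochondrial sum, camera, adjusted p = 0.15). TSC22D3, also known as GILZ, rose from 0.322 ± 0.0331 to 1.89 ± 0.0548 FPKM (SD, n = 5; log2 fold change 2.24 ± 0.058 SE, adjusted p = 5.93e-13). FKBP5, a classical target of glucocorticoid and progesterone receptors, measured 3.32 ± 0.106 FPKM in DMSO and 3.44 ± 0.188 FPKM in HPC (log2 fold change 0.05 ± 0.041 SE, adjusted p = 0.251), and turned to -0.11 with libraries scaled to the non-mitochondrial sum (adjusted p = 0.0208). The progesterone receptor gene PGR was not analysed here. Of the 4 tested steroid receptor genes, NR3C1, the glucocorticoid receptor, fell from 2.42 ± 0.0594 to 1.21 ± 0.0825 FPKM, and PGRMC1, a membrane-associated progesterone receptor component, from 58.7 ± 0.662 to 42.6 ± 1.21 FPKM. The other members, PAQR7 (log2 fold change 0.07, adjusted p = 0.0498) and PGRMC2 (adjusted p = 0.139), were named after their values were seen. Of the 6 tested steroid metabolism genes, 1 was higher, 4 lower and 1 did not pass (median -0.25, or -0.41 with the non-mitochondrial sum, camera, adjusted p = 0.421).

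Among 23 genes of cholesterol synthesis and uptake, 13 were higher, 8 lower and 2 did not pass, without a call (median log2 fold change 0.24, or 0.08 with the non-mitochondrial sum, camera, adjusted p = 0.281). HMGCS1, an early enzyme of the pathway, rose from 21 ± 1.29 to 35.8 ± 2.54 FPKM (SD, n = 5). INSIG1, whose product retains the sterol regulator SCAP in the endoplasmic reticulum, measured 34.4 ± 0.742 FPKM in DMSO and 35.7 ± 2.12 FPKM in HPC (log2 fold change 0.05 ± 0.037 SE, adjusted p = 0.205). Without HPC replicate 4, INSIG1 passed the threshold at 0.08 (adjusted p = 0.0177), as it did without both libraries numbered 4 (0.09, adjusted p = 0.0207). It turned to -0.07 after quantile normalization (adjusted p = 0.0409) and to -0.12 with the non-mitochondrial sum (adjusted p = 0.00789, within a range of 0.00789 to 0.621). ABCA1, a cholesterol exporter, was under the filter on low values, at 0.868 ± 0.134 FPKM in DMSO and 0.204 ± 0.0513 FPKM in HPC, and its values did not overlap. The liver X receptor list, to which it belongs, had 4 tested members with a median of 0.24, or 0.07 with the non-mitochondrial sum, and was too short for a list test.

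On the scale with 0.1 FPKM added, on which the rule ranked them, the largest single rises were found for GDF15, a stress-induced cytokine gene, from 0.258 ± 0.157 to 23.7 ± 2.47 FPKM (SD, n = 5; log2 fold change 6.16 ± 0.279 SE, adjusted p = 2.24e-08), and ATF3, from 0.346 ± 0.0672 to 20.1 ± 1.2 FPKM. They were followed by SPRR2D, DDIT3, LCE1F, BEX2, CHST1, HSPA6, INHBE and ATP6V0D2, with log2 fold changes between 4.83 and 5.31. The order depends on the value added: over the alternatives the log2 fold change of GDF15 ranged from 4.30 to 6.72, that of SPRR2D from 2.38 to 9.02, that of LCE1F from 2.15 to 8.42 and that of ATP6V0D2 from 2.01 to 8.30. ATP6V0D2 had 8 reads in the 5 DMSO libraries and 1758 in the 5 HPC libraries, a ratio of 239 (95% counting interval 121 to 553). LCE1F had 0 reads in the 5 DMSO libraries and 425 in the 5 HPC libraries, which makes it 154-fold higher against a floor of 3 reads over the group, with a lower limit of 125-fold from the counting interval of both groups. SPRR2D and LCE1F belong to epidermal gene families with near-identical members and their levels are uncertain. On the same scale the largest falls were those of KRT15, TMEM88B, MYBPH, COL1A2, BRINP3, MEST, S100A4, SEMA6B, MCHR1 and ANK1, with log2 fold changes between -5.53 and -3.99. Over the alternatives KRT15 ranged from -6.24 to -3.47, MYBPH from -9.18 to -2.17, TMEM88B from -6.71 to -2.76 and MCHR1 from -7.33 to -1.46, so this order is not fixed either. S100A4, a calcium-binding protein gene used as a mesenchymal marker, fell from 235 ± 14.4 to 13.2 ± 1.12 FPKM, the collagen gene COL1A2 from 25.8 ± 0.866 to 0.809 ± 0.101 FPKM and the keratin gene KRT15 from 11.9 ± 0.341 to 0.166 ± 0.0581 FPKM.

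Mesenchymal genes as a list were not called, with 3 higher, 5 lower and 1 of 9 not passing (median log2 fold change -0.97, camera, adjusted p = 0.257). Nor were 10 epithelial genes, with 5 higher, 4 lower and 1 not passing (median 0.04, which turned to -0.13 with the non-mitochondrial sum and -0.04 after quantile normalization, adjusted p = 0.995). Markers of cell types other than the cell line were mostly below 1 FPKM in both groups, namely 16 of 17 leukocyte, 11 of 13 fibroblast, 7 of 11 endothelial, 8 of 8 pancreatic acinar and 10 of 12 endocrine islet markers. The mean log2 level of the fibroblast markers was -2.47 ± 0.0415 in HPC and -1.91 ± 0.0083 in DMSO (SD, n = 5, exact permutation p = 0.00794, adjusted p = 0.0129), which includes COL1A2. For the endothelial markers it was -1.57 ± 0.0293 and -1.01 ± 0.0208, for the leukocyte markers -2.45 ± 0.0199 and -2.01 ± 0.0709 and for the acinar markers -2.51 ± 0.0768 and -2.96 ± 0.076, each with the same p. The endocrine islet markers measured -1.79 ± 0.0439 and -1.75 ± 0.034 (exact permutation p = 0.183, adjusted p = 0.198). Medians over the members went against the means for acinar markers (0.0027 FPKM in HPC, 0.0083 in DMSO) and fibroblast markers (0.0053 and 0.0023). For leukocyte and endothelial markers they went the same way as the means. CD68, the leukocyte marker at 1 FPKM or more, rose from 2.75 ± 0.358 to 9.77 ± 1.15 FPKM.

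The remaining lists were not called in the main fit, which shifted 9 lists up. Some lists not called there passed under alternatives, and which ones is not reported here. With the non-mitochondrial sum 12 lists were shifted up, and without any 1 of the DMSO libraries 11 were. Among the longer ones, 37 of 65 cytosolic ribosomal protein genes were lower and 21 higher (median log2 fold change -0.08, or -0.25 with the non-mitochondrial sum, camera, adjusted p = 0.179). Of 31 lysosome and autophagy genes 16 were higher and 11 lower (median 0.15, which turned to -0.02 with the non-mitochondrial sum, adjusted p = 0.244). Further, 15 of 25 apoptosis regulators were higher and 8 lower (adjusted p = 0.122), and 11 of 21 glycolysis genes were lower and 6 higher (adjusted p = 0.219). Of 18 ERK pathway feedback genes 11 were higher and 5 lower (adjusted p = 0.122), of 16 ferroptosis and iron genes 10 were higher and 6 lower (adjusted p = 0.122), and of 14 fatty acid synthesis genes 4 were higher and 9 lower (adjusted p = 0.166). TGF-beta targets split into 8 higher and 3 lower (adjusted p = 0.091). YAP and TEAD targets split into 8 higher and 5 lower (median 0.14, which turned to -0.02 with the non-mitochondrial sum, adjusted p = 0.51), and tubulins and microtubule genes into 7 and 7 (median -0.01, which turned to 0.01 with median-of-ratios scaling, adjusted p = 0.764). Xenobiotic metabolism and efflux genes split into 3 higher and 0 lower of 6 (adjusted p = 0.132), and replication dependent histones into 2 higher and 3 lower of 8 (adjusted p = 0.75). The WNT beta-catenin list had 4 tested members with a median of 0.12, which turned to -0.04 with the non-mitochondrial sum, and was too short for a list test. The median and mean fold changes differed in sign for the epithelial, MHC class I and histone lists (medians 0.04, 0.02 and -0.26, means -0.24, -0.16 and 0.01).

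The FPKM total was 129000 ± 975 in HPC and 126400 ± 1550 in DMSO (SD, n = 5, exact permutation p = 0.0238, adjusted p = 0.0281), and the number of genes at 1 FPKM or more was 8631 ± 20.6 and 8883 ± 4.04 (exact permutation p = 0.00794, adjusted p = 0.0129). The 10 most abundant genes held 21.8% ± 0.737 and 23.2% ± 0.694 of the total (exact permutation p = 0.0238, adjusted p = 0.0281), ribosomal protein genes 5.88% ± 0.0891 and 6.10% ± 0.0562 (exact permutation p = 0.0159, adjusted p = 0.0229), and replication dependent histones 0.0554% ± 0.0024 and 0.0867% ± 0.0077 (exact permutation p = 0.00794, adjusted p = 0.0129). The histone values come from poly(A)-selected RNA, and histone levels in total RNA were not measured. The second principal component, with 1.7% of the variance, did not separate the groups (exact permutation p = 0.984). The call on the FPKM total was lost without DMSO replicate 1, 3, 4 or 5 (difference 2683, 2241, 2363 and 2277, adjusted p = 0.0563, exact permutation) and without HPC replicate 3 (2557, adjusted p = 0.0516), and that on the 10 most abundant genes without HPC replicate 2 or 3 (-1.21 and -1.36 points, adjusted p = 0.0563). Compared by medians instead of means, the library measures that had passed, marker levels and mitochondrial share included, all had an adjusted p of 0.0563 by the exact permutation test. Different assignments can share the same medians, and 0.0563 was the lowest adjusted p this test could give these measures. The comparison by medians therefore could not decide.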

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

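The results below were picked out because 1 library lay far from the other 4 of its group, by a gap above 0.71 of the group's range. Of 215 groups of 5 values looked at, 12 (5.6%) did so, and chance gives about 5%. They are given as values, with no explanation, and no test was added after they were seen.

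The share of the FPKM total in mitochondrially encoded genes was 23.8% in DMSO replicate 2 against 21.9% to 22.5% (others). In HPC libraries, HMOX1 stood at 43.3 FPKM in replicate 3 (others 40.4 to 40.7), MYC at 19.3 FPKM in replicate 4 (others 20.7 to 21.2), INHBE at 6.61 FPKM in replicate 5 (others 5.70 to 5.91), KDM3A at 3.73 FPKM in replicate 1 (others 3.36 to 3.46), XBP1 at 42.0 FPKM in replicate 4 (others 44.3 to 45.2) and TMEM88B at 0.709 FPKM in replicate 4 (others 0 to 0.119). In DMSO libraries, BEX2 stood at 0.931 FPKM in replicate 1 (others 0.439 to 0.553), RIGI at 7.74 FPKM in replicate 1 (others 8.32 to 8.50), MCM4 at 7.58 FPKM in replicate 2 (others 7.89 to 8.0), FHL2 at 1.75 FPKM in replicate 4 (others 1.95 to 2.02) and XBP1 at 6.22 FPKM in replicate 5 (others 6.74 to 6.81).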

How the results depend on the processing

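The voom, non-mitochondrial-sum and length-and-GC alternatives were chosen after seeing the data. Without a filter, 2806 genes instead of 1861 were at least 1.5-fold lower, since more genes were tested. With a filter of at least 5 FPKM, 1969 genes were higher and 1836 lower, and 809 and 848 by at least 1.5-fold, since fewer genes were tested. At a threshold of 0.01, 4 lists were shifted down instead of 7. Camera with an estimated correlation called 0 lists up and 0 down, and fry 19 up and 17 down. Fry thereby called every tested list, so it does not tell the lists apart here. It called the epithelial and MHC class I lists down (fry, adjusted p = 0.000264 and 0.000727). Camera gave both the opposite direction with an adjusted p of 0.995. Voom on the recovered reads called 3926 genes higher and 4101 lower. Leaving out 1 library, 3587 to 3879 genes were higher and 3564 to 4087 lower, with 9 to 11 lists shifted up and 6 to 7 down. The filter still asked for 5 libraries. Thus 8655 to 8660 genes were tested without a DMSO library and 8861 to 8867 without an HPC library, instead of 9150. These counts therefore reflect the filter as well as the library left out. The log2 fold change of INSIG1, which did not pass at 0.05, became -0.072 after quantile normalization and -0.116 with libraries scaled to the non-mitochondrial sum, and that of FKBP5 -0.112 with the latter. The cause was not tested.

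Compared by medians, the library measures that had passed kept their direction with an adjusted p of 0.0563, the lowest that the exact permutation test by medians could give them. They were 3229 for the FPKM total, -258 for genes at 1 FPKM or more, -1.33 points for the 10 most abundant genes, -7.73 for mitochondrially encoded genes, -0.230 for ribosomal protein genes and -0.0306 for histones. In mean log2 level they were -0.466 for leukocyte, -0.574 for fibroblast, -0.551 for endothelial and 0.411 for acinar markers, with 83.7 for principal component 1. Component 2, which had not passed, turned to -1.15. Leaving out 1 library, the FPKM total difference ranged from 2241 to 3164 and lost its call without DMSO replicates 1, 3, 4 or 5 or HPC replicate 3. The share of the 10 most abundant genes ranged from -1.71 to -1.13 points and lost it without HPC replicates 2 or 3, and principal component 2 ranged from -1.90 to 2.26, with no call in any.

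Whether replicate numbers pair the libraries could not be settled from 5 numbers. Deviations of same-numbered libraries correlated at -0.06, 0.07, 0.20, 0.02 and 0.14, and own number was the best partner for 2 of 5. With a replicate block 3892 genes were higher and 4077 lower, and 7930 calls were shared with the unblocked fit. The replicate block also moved the actin list to an adjusted p of 0.0548, within a range of 0.0211 to 0.11 at the preset camera correlation, and changed the call of none of the other called lists or the genes carried through the alternatives. Only the called lists and the tested genes of the rule were carried through the alternatives that keep camera at its preset correlation. Of their values, 3244 kept their direction and side of the threshold, 25 lost the threshold, 2 gained it and 3 reversed. Both gains were those of INSIG1. Most of these genes and lists were chosen by small p or large changes in these data, so most could be expected to keep their call. A list not called in the main fit could not count as a gain. A gene that an alternative's filter no longer tested has no value there and is not in these counts. No list test was run with the unmoderated unequal-variance test per gene.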

Other observations

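Except for the splits of the libraries, all tests in this part were chosen after the data had been seen, the removal of the length and GC trend included. Gene families formed by name, 18 in all, were tested with camera in the same fit. Some were called, and with an estimated correlation none was (lowest adjusted p = 0.139). Some families share members with the gene lists. All 5 tested EGF receptor ligand genes rose with HPC (median log2 fold change 2.90, camera, adjusted p = 0.00508; adjusted p = 0.139 with an estimated correlation), with HBEGF from 1.04 ± 0.185 to 22.9 ± 1.91 FPKM (SD, n = 5), EPGN from 2.34 ± 0.18 to 18.1 ± 0.674 and AREG from 19.3 ± 1.69 to 202 ± 3.70. Of 12 amino acid transporter genes 11 rose and 1 fell (median 1.29, adjusted p = 0.00142; adjusted p = 0.139 with an estimated correlation), led by SLC3A2 from 2.58 ± 0.114 to 48.4 ± 4.45 FPKM and SLC7A5 from 12.3 ± 1.12 to 91.4 ± 1.84, both also members of the ATF4 list. Of 18 aminoacyl-tRNA synthetase genes 14 rose and 4 fell (median 0.78, adjusted p = 0.00142; adjusted p = 0.348 with an estimated correlation), with GARS1 from 31.6 ± 0.947 to 135 ± 0.922 FPKM, while QARS1 fell from 3.31 ± 0.0868 to 1.2 ± 0.0407.

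Of 11 dual specificity phosphatase genes 10 rose and 1 fell (median 1.00, camera, adjusted p = 0.00142; adjusted p = 0.139 with an estimated correlation). Of 17 genes of the signal recognition particle and translocon 14 rose and 3 fell (median 0.55, adjusted p = 0.011; adjusted p = 0.529 with an estimated correlation). Of 234 genes with a ZNF symbol, an opposite-strand and a readthrough gene included, 134 rose and 64 fell (median 0.25, or 0.08 with the non-mitochondrial sum, adjusted p = 0.00808; adjusted p = 0.139 with an estimated correlation). Among families that fell were 13 Fanconi and recombination genes, with 12 lower (median -0.76, adjusted p = 0.00142; adjusted p = 0.156 with an estimated correlation), and 15 genes of condensin, cohesin and the SMC5/6 complex, with 12 lower and 1, SMC6, higher (median -0.87, adjusted p = 0.00142; adjusted p = 0.216 with an estimated correlation). Kinesins had 15 lower and 6 higher of 24 (adjusted p = 0.0437; adjusted p = 0.395 with an estimated correlation). The other 9 families were not called, with adjusted p from 0.0658 to 0.835.

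In the number of genes called between HPC and DMSO, chance in the division of these 10 libraries could be excluded: of 100 splits of the 10 libraries into 5 and 5, drawn from 126, only the real one (1 split) called as many genes, 8021, and the highest of the others called 1. Every other split mixes libraries of both groups, so any steady difference between the groups, whatever its source, would give this result. Removing a loess trend on transcript length and GC content from each library left 95.6% of the called genes called in the same direction, which argues against that trend as the whole cause. The labels name the treatment as the difference between the groups and give no batch or culture day, and an effect of HPC stays as a hypothesis.

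The mitochondrially encoded mRNAs changed unequally. Less mitochondrial RNA as a whole would lower the 12 heavy-strand genes alike, yet their log2 fold changes spanned 2.23, against a largest SE of 0.073. MT-ATP8 and MT-ATP6 overlap, as do MT-ND4L and MT-ND4, so the genes are not all separate points. The Spearman rho across genes was -0.43 with the distance from the start of the heavy-strand transcript (permutation p = 0.16, adjusted p = 0.31 over 2 correlations) and 0.31 with gene length (permutation p = 0.31, adjusted p = 0.31), which decides nothing, and the test was replaced after this was seen. The best steady decline with distance left a scatter of 0.48 (root mean square), and the best steady rise or fall with length one of 0.56, against a largest SE of 0.073, which argues against either as the whole cause and leaves a part in it open. Altered stability or polyadenylation of single mRNAs, and reads shared with nuclear copies, were not tested and stay open.

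The large falls of S100A4, COL1A2 and KRT15 raise the question whether other cells contributed to the libraries. Only 4 genes had 0 reads in all libraries of a group and at least 1 FPKM in the other, which decides nothing about another cell line present in both groups at unequal shares, since its genes would stay above 0, as COL1A2 did in HPC at 0.809 FPKM. Fibroblasts among the DMSO cells would bring other collagens and proteoglycans with COL1A2 (25.8 FPKM in DMSO), but the highest of COL1A1, COL3A1, DCN and LUM there was 0.22 FPKM. This test replaced an earlier one after its result was seen: of 61 markers of other cell types 5 (COL1A2, CDH5, ENG, EGFL7 and SCG2) were at 1 FPKM or more in DMSO and lower with HPC, while CD68, COL6A3, ROBO4 and ENO2 rose, a count that left the question open. Another cell line at unequal shares and a change of these genes within the cell line both stay open.

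Some genes that overlap another were above 0 in only a part of the DMSO libraries, and how reads were divided between such genes was not tested. SLC25A32 (chromosome 8, 103398635 to 103415189) measured 0.776 FPKM in DMSO replicate 1 and 2.99 to 3.21 FPKM in the other DMSO libraries, and the overlapping gene ENSG00000285982 measured 8.57 FPKM in that library and 0 in the other 9. MIF overlaps ENSG00000251357, which measured 58.3 FPKM in DMSO replicate 2 and 0 in the other 9 libraries, while MIF had 44.0 FPKM there and 55.4 to 85.2 FPKM in the other DMSO libraries. With HPC, MIF ranged from 39.5 to 55.8 FPKM. BLOC1S5-TXNDC5 measured 2.82, 18.8 and 8.54 FPKM in DMSO replicates 2, 3 and 5 and 0 in the other 7 libraries. The overlapping gene TXNDC5 measured 42.1, 37.9 and 40.5 FPKM in those replicates and 43.0 and 42.8 FPKM in DMSO replicates 1 and 4. These genes were named after their values were seen, and values of genes that overlap another on the same strand are uncertain.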
